A study of Mus musculus with 6 samples.

How the data were processed

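ATAC-seq libraries were made from NMuMG mouse mammary epithelial cells in 3 groups of 2 biological replicates, treated with DMSO or with BRM014 for 6 h or 30 h. The labels' extraction protocol also describes cells treated with TGFβ, a treatment that no sample label in this series carries. How long the DMSO cells were treated is given only by the name of their list, as 30 h, and not by the sample labels, so both times were compared with that list. Per the labels, each deposited peak list was made from both replicates of a group, so a list was treated as 1 pooled sample. Peak calling used MACS2 2.1.2 and coordinates were on the mouse build mm9, per the submitters' processing notes. The aligner, the read filters, any shift of reads for the transposase and the options of the caller were not given in the sources used here.

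Each list gave 5 values per entry. The deposited score ran from 540 to 1000, and 76.5% of DMSO entries, 65.0% of 6 h entries and 70.3% of 30 h entries stood at 1000. The lowest score, 540, is the value that the IDR program (irreproducible discovery rate between replicates) writes at an IDR of 0.05, but no label says that the authors used it. The ratio in the lists is the fold enrichment at the summit over local background, as the authors' caller deposited it. The deposited -log10 p and -log10 q of each entry were taken as the authors' own, with no scaling between lists, and the lowest -log10 p was 2.00 in the DMSO list. The last column deposited by the authors is the summit position as an offset from the start. These values were used to describe, rank and filter regions within their own list, and no fold change of fold enrichment between lists was computed.

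Entries that share an interval because it has several summits were merged into 1 region with the highest fold enrichment, -log10 q and score of its entries. A region counted as shared when it overlapped a region of the other list by at least 1 bp, and as missing or new otherwise. A missing region was not called, which is not the same as closed. Shares were given with 95% Wilson intervals, and differences and weighted shares with 95% intervals from the binomial variances. Ratios of counts and the median of pileups found have bootstrap intervals. All cover counting error only and treat regions as independent. No test between treatments was made, since there was 1 list per group. Regions were ranked in deciles on fold enrichment, and shares by width, spacing and summit number were also averaged with equal weights over these deciles. Overlap after random circular shifts of a list along its chromosomes, 100 times, was 1.49% of DMSO regions with the 6 h list and 2.09% with the 30 h list. Neighbouring regions were compared with 1000 shuffles of the missing regions within deciles.

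Relative depth was recovered from the lists. MACS2 by default writes the fold enrichment as pileup plus 1 over background plus 1 and takes p from a Poisson distribution, and these defaults were assumed. A whole-number pileup and a background were therefore solved for each entry, and matched its deposited -log10 p within 0.001 for 100% of entries. The lowest background of a list was assumed to be its genome average, which scales with depth, and all values at equal expected pileup rest on that. It was 3.37 for DMSO, shared by 7641 entries, 2.12 at 6 h, shared by 2052, and 2.72 at 30 h, shared by 5970. The summit pileup of each region times the ratio of these values gave the pileup expected in another list. DMSO regions were then compared with regions of the other treated list in 4 bins per doubling of expected pileup that held at least 50 regions of each, weighted to the DMSO regions. At an expected pileup of at least 256, the limits of the difference came from the Wilson limits of both shares, and the highest pileup found in each DMSO region was divided by that expected, with missing regions as 0.

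The comparisons, the overlap rule, the deciles of fold enrichment, and the rule for the regions named were fixed before the data were examined. That rule took the 10 regions with the highest fold enrichment among DMSO regions missing at both times and among 30 h regions without a DMSO region. It also took the 5 windows of 1 Mb with the most DMSO regions missing at 30 h, the 5 with the largest share among windows with at least 20 DMSO regions, and the 5 with the most new regions at 30 h. The ranking on -log10 q, the classes of summit number, the expected pileup, the pileups found over those expected and the simulation against the shared DMSO list were added after the data were examined. The planned comparison of promoters with distal regions, 14 gene lists and 23 consensus motifs were not used, because the gene table at hand is of the build GRCm38 and the lists are on mm9, and coordinates were not converted. Width, spacing, chromosomes and windows took their place, as planned for that case. The lists held chromosomes 1 to 19 and X.

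The overlap and neighbour steps were tested on simulated data made from the 42310 DMSO regions: 100% of removed regions were found missing, and 2000 of 2000 added regions were found new. Of 20 simulated sets of clustered losses, 20 lay above all shuffles, and of 20 sets without clustering 19 lay inside the central range. The losses without clustering depended only on the deciles of fold enrichment that the shuffles keep. Losses that also follow -log10 q or spacing were therefore not covered by these simulations. The recovery of pileups was tested on simulated entries, of which 100% were recovered. The alternatives were an overlap of at least 50% of the counted region, the summit inside a region, a -log10 q of at least 5, the 25922 strongest regions of every list, every entry counted singly, and all chromosomes. Those added later were a score of 1000, regions within 500 bp counted as shared, deciles of -log10 q, and expected -log10 p in place of expected pileup. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.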

Results

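Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in NMuMG cells, an established epithelial cell line from normal mouse mammary gland. Cells received the vehicle DMSO or BRM014, an inhibitor of the ATPase subunits of the SWI/SNF chromatin remodelling complexes, for 6 h or 30 h. The 6 samples formed 3 groups of 2 biological replicates, and the authors made 1 peak list per group from both replicates together. There were therefore no replicate values to compare. By the name of its list DMSO was given for 30 h, so the 6 h list had no vehicle control of its own time. Intervals beside a share are 95% Wilson intervals. Those of differences and of weighted shares are 95% intervals from the binomial variances. All cover counting error only, and how far 2 DMSO lists would differ from each other is not known. The DMSO list held 75531 entries that merged into 42310 regions, covering 30.2 Mb with a median width of 677 bp. The 6 h list held 48321 entries in 25922 regions, covering 17.9 Mb with a median width of 656 bp. The 30 h list held 67413 entries in 38422 regions, covering 25.1 Mb with a median width of 601 bp. The authors' fold enrichment had a median of 13.0 in the DMSO list, 13.0 in the 6 h list and 12.6 in the 30 h list. Read totals were not analysed here, but the lowest background in each list, recovered from the deposited fold enrichment and -log10 p, was taken as a measure of relative depth, which was 63.0% of DMSO for the 6 h list and 80.7% for the 30 h list. Regions are named by chromosome and position in the mouse build mm9, because no gene annotation of that build was used here.

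The first comparison asked which accessible regions of vehicle-treated cells were no longer called after 6 h of BRM014. Of the 42310 DMSO regions, 18452 had no overlapping region at 6 h, a share of 43.6% (43.1 to 44.1%). Losses fell mainly on weak and narrow regions: the missing regions had a median fold enrichment of 10.5 and a median width of 552 bp, against 15.3 and 789 bp for those still called. In the decile of DMSO regions with the lowest fold enrichment 69.4% were missing (68.0 to 70.7%), and in the decile with the highest 12.7% (11.7 to 13.7%). Ranked on the authors' -log10 q instead, a ranking chosen after the data were examined, the share went from 89.3% in the weakest decile (88.4 to 90.2%) to 1.32% in the strongest (1.02 to 1.71%). At similar -log10 q the share did not fall steadily with fold enrichment. In the middle quintile of -log10 q it was 40.4% in the lowest and 47.9% in the highest quintile of fold enrichment. In the weakest quintile of -log10 q it was 85.9% in the lowest and 80.3% in the middle quintile of fold enrichment. DMSO regions were also compared with 30 h regions whose summits had the same pileup expected at the depth of the 6 h list. In bins of equal expected pileup, 43.3% of DMSO regions were missing at 6 h, against 35.8% of 30 h regions weighted to the same bins, a difference of 7.57 percentage points (7.05 to 8.09). The difference lay in the middle and upper bins: between pileups of 128 and 152, 18.1% of DMSO regions and 6.04% of 30 h regions were missing, whereas between 32.0 and 38.1 the shares were 78.2% and 79.3%. The total share depended on list length and on the score. With the 25922 strongest regions of every list the share missing at 6 h was 23.1%, and among DMSO regions at the highest score of 1000 it was 28.5%.

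**Figure D1:**
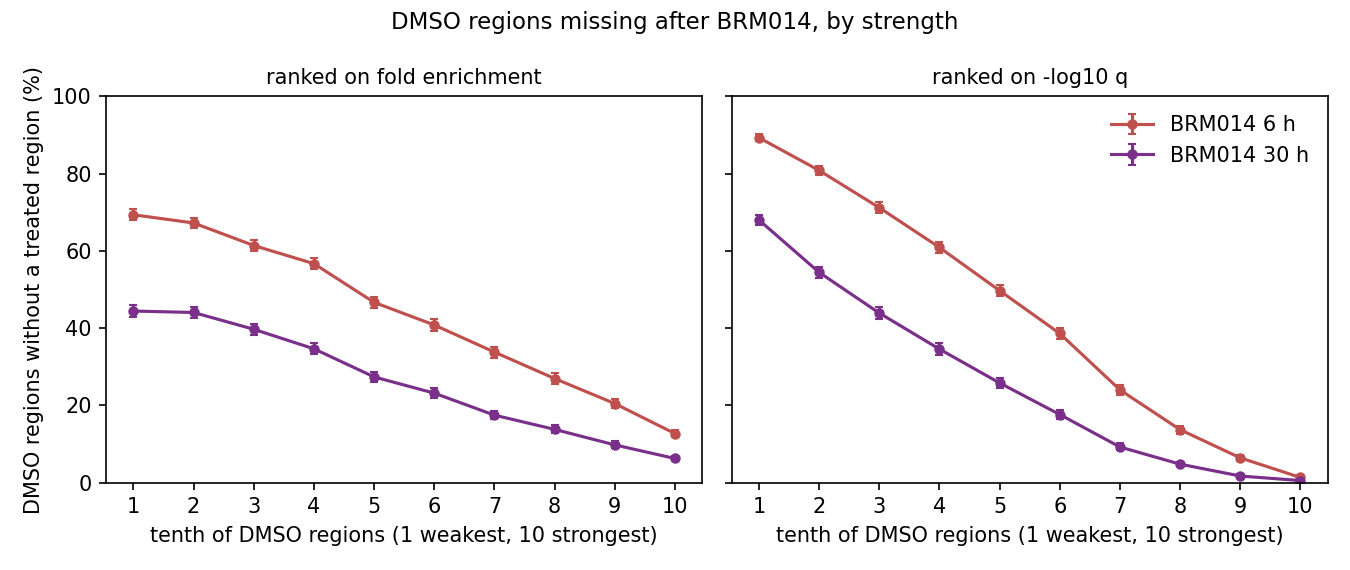
Share of DMSO regions without an overlapping region at 6 h (red) and 30 h (purple) of BRM014, in percent, for deciles of the DMSO list ranked on the authors' fold enrichment (left) and -log10 q (right), with 95% Wilson intervals as bars. The share at 6 h falls from 69.4% to 12.7% on the left and from 89.3% to 1.32% on the right.

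The second comparison put the same question after 30 h. Here 11027 of the 42310 DMSO regions had no overlapping region, 26.1% (25.6 to 26.5%), fewer than at 6 h. The missing regions had a median fold enrichment of 10.1 and a median width of 532 bp, against 14.3 and 737 bp for those still called. By fold enrichment the share missing went from 44.4% in the weakest decile (42.9 to 45.9%) to 6.24% in the strongest (5.55 to 7.01%), and by -log10 q from 68.0% (66.6 to 69.4%) to 0.520% (0.344 to 0.786%). At equal expected pileup 25.1% of DMSO regions were missing at 30 h, against 9.14% of 6 h regions, a difference of 16.0 points (15.4 to 16.6). The 6 h list reached less far down in expected pileup than the DMSO list, so the lowest bins held few 6 h regions. With the 25922 strongest regions of every list the shares missing at 6 h and 30 h were 23.1% and 19.9%, and among DMSO regions at a score of 1000 they were 28.5% and 14.1%.

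**Figure D2:**
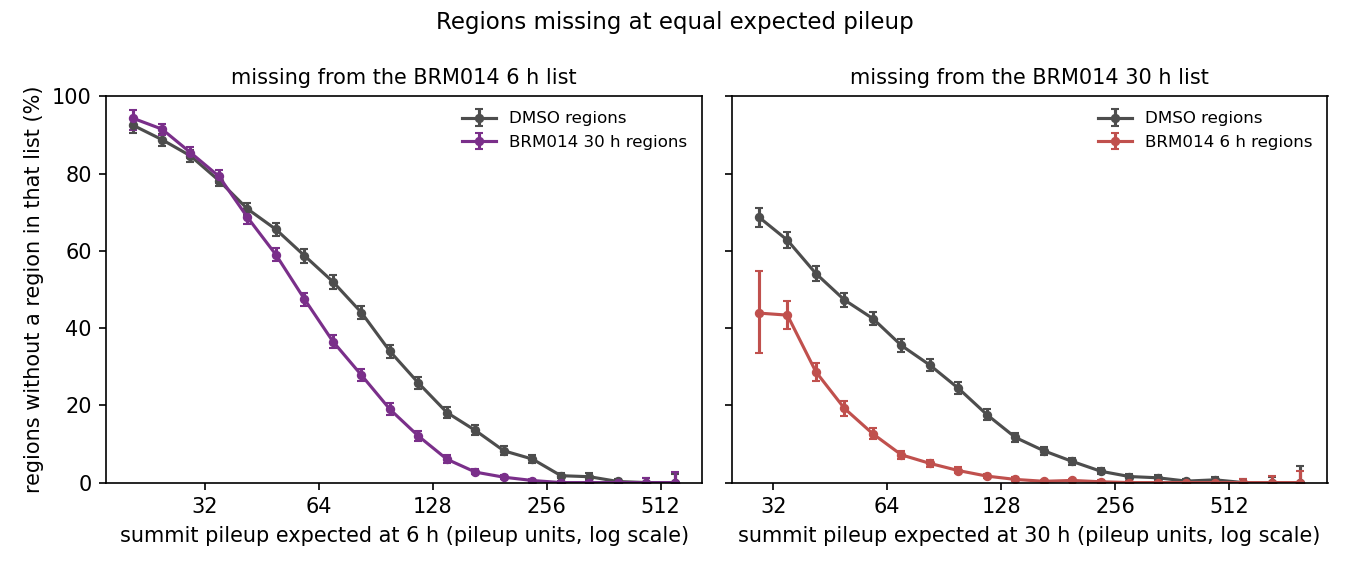
Share of regions missing from the 6 h list (left) and from the 30 h list (right), in percent, against the summit pileup expected at the depth of that list (log scale), for DMSO regions (grey) and for regions of the other treated list (purple or red), with 95% Wilson intervals. Over all bins DMSO regions are missing more often by 7.57 points on the left, where the lowest bins do not lie above, and by 16.0 points on the right.

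The 3 lists came from separate samples, not from the same cells followed over time. Each DMSO region was placed in 1 of 4 classes by its overlap with the treated lists. At both times 22871 regions were still called (54.1%), 8412 were missing at 6 h only (19.9%), 987 at 30 h only (2.33%) and 10040 at both times (23.7%). Of the regions missing at 30 h, 91.0% were also missing at 6 h (90.5 to 91.6%), and of those missing at 6 h, 45.6% were called at 30 h (44.9 to 46.3%). The 6 h list had 63.0% and the 30 h list 80.7% of the depth of the DMSO list, so a region missing at 6 h only need not have been regained by 30 h. Losses independent of each other would have put 4809 regions in the class missing at both times, or 5886 within deciles of fold enrichment and 7606 within deciles of -log10 q. Both losses were counted against the same DMSO list. In 1000 simulations against that list, in which each region was missing as often as regions of the other treated list at equal expected pileup, the class held 3181 regions on average and 3325 at most. The simulated shares missing, 36.1% at 6 h and 9.76% at 30 h, came from 1 treated list set against the other and lay below the shares observed. The simulated count is therefore not a measured count without treatment, and the excess over it does not measure how far the same regions were lost. The class shrank to 14.9% of DMSO regions with 25922 regions in every list and to 12.3% among regions at a score of 1000. The 10040 regions missing at both times had the lowest median fold enrichment of the 4 classes, 9.93, against 15.5 for the regions called at both times.

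Among the DMSO regions missing at both times, the 10 with the highest fold enrichment lay on 9 chromosomes, each within the strongest decile by that measure. By -log10 q they ran from 132 to 435, and only the region on chromosome 3 lay in the strongest decile, which began at 328. The first by fold enrichment was this region on chromosome 3 from 21484483 to 21485216, with a fold enrichment of 31.3 and a -log10 q of 435. It was followed by a region with 3 summits on chromosome 4 from 93710197 to 93710998, at a fold enrichment of 30.0. The next, on chromosome 2 from 50888003 to 50888526, had a fold enrichment of 29.5. On chromosome 15 the region from 44210651 to 44211178 had a fold enrichment of 28.8, and on chromosome 1 that from 16189189 to 16189969 one of 27.9. The other 5 lay on chromosome 12 from 57343720 to 57344278, chromosome 8 from 43272199 to 43272830, chromosome 14 from 46699175 to 46699590, chromosome 5 from 42320948 to 42321481, and chromosome 8 from 55526368 to 55527058, with fold enrichments from 26.5 to 27.7. None of these 10 had a treated region within 500 bp.

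Regions called only after treatment were fewer than the DMSO regions missing, with treated lists shorter than the DMSO list, and were mostly weak. At 6 h, 1923 of 25922 regions had no DMSO region, 7.42% (7.11 to 7.74%), and at 30 h 6894 of 38422, 17.9% (17.6 to 18.3%). Of the new 6 h regions 60.0% were also called at 30 h (57.7 to 62.1%), while 16.8% of the new 30 h regions had been called at 6 h (15.9 to 17.7%). By fold enrichment within the 30 h list, 33.1% of the weakest decile was new (31.6 to 34.6%) and 0.755% of the strongest (0.526 to 1.08%). The strongest new region at 30 h lay on chromosome 15 from 13314560 to 13314981, with a fold enrichment of 28.8 and a -log10 q of 176. Others were on chromosome 11 from 92454003 to 92454703, with a fold enrichment of 26.4, on chromosome 6 from 97912379 to 97912713, at 25.7, on chromosome 7 from 50678405 to 50678877, at 25.3, and on chromosome 12 from 55975722 to 55976111, at 24.5. The remaining 5 of the 10 strongest lay on chromosome 13 from 23722599 to 23722987, chromosome 14 from 120868508 to 120869005, chromosome 2 from 91139173 to 91139821, chromosome 16 from 44002013 to 44002542 and chromosome 16 from 11297640 to 11298318. Of these 10 regions, 4 also had a region at 6 h. With 25922 regions in every list the order of the times turned, with 22.3% new at 6 h and 19.4% at 30 h, and among regions at a score of 1000 the shares were 0.903% and 4.62%.

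The widest regions, and those with the most summits, were kept most often. In the narrowest quartile of DMSO regions, 150 to 492 bp, 68.5% were missing at 6 h (67.7 to 69.4%) and 44.1% at 30 h (43.1 to 45.0%). In the widest quartile, 888 to 2580 bp, 16.4% were missing at 6 h (15.7 to 17.1%) and 7.71% at 30 h (7.22 to 8.24%). With equal weights over deciles of fold enrichment the 30 h shares were 34.6 ± 1.12% in the narrowest and 9.43 ± 0.729% in the widest quartile (95% intervals), and over deciles of -log10 q 25.7 ± 0.790% and 18.7 ± 1.21%. By -log10 q the quartiles between them had the most missing at 30 h, 29.2 ± 0.713% and 27.9 ± 0.885%, so the share did not fall steadily with width. Of the 20724 regions with a single summit 35.4% were missing at 30 h (34.8 to 36.1%), and of the 2601 with at least 4 summits 4.38% (3.66 to 5.24%). Weighted equally over deciles of -log10 q these shares were 28.8 ± 0.514% and 11.1 ± 2.05%. Spacing showed less. At 6 h 44.4% of the quartile of regions closest to another DMSO region were missing (43.4 to 45.3%) and 44.0% of the most isolated quartile (43.1 to 45.0%). With equal weights these shares were 28.6 ± 0.906% and 53.6 ± 1.13% over deciles of fold enrichment, and 42.0 ± 0.742% and 43.5 ± 0.750% over deciles of -log10 q. At 30 h 25.2% of the closest quartile were missing (24.4 to 26.0%), and 28.5% of the most isolated quartile (27.6 to 29.4%). The difference between these quartiles at 30 h was 22.3 points within deciles of fold enrichment and 4.28 points within deciles of -log10 q. By fold enrichment it was 7.67 points with 25922 regions in every list and 10.0 points at a score of 1000. At 6 h the difference by fold enrichment was 25.1 points, 5.75 points with 25922 regions in every list and 14.0 points at a score of 1000.

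Chromosomes differed by a few points. The share of DMSO regions missing at 30 h was lowest on chromosome 7, 22.9% (21.4 to 24.6%), chromosome 19, 23.3% (21.3 to 25.4%), and chromosome 11, 24.0% (22.4 to 25.5%). It was highest on the X chromosome, 29.5% (26.9 to 32.3%), chromosome 13, 29.4% (27.4 to 31.4%), and chromosome 14, 29.0% (26.7 to 31.5%). With equal weights over deciles of -log10 q, chromosome 11 was at 23.7 ± 1.32% and chromosome 13 at 29.0 ± 1.70%, the lowest and the highest of the 20 chromosomes.

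Windows of 1 Mb varied more. Among the 914 windows with at least 20 DMSO regions the median share missing at 30 h was 24.2%, and the standard deviation between windows was 10.5 points, against a mean of 8.13 and a highest value of 8.71 in 1000 shuffles within deciles of -log10 q. The window from 52000001 to 53000000 on chromosome 13 had the most missing regions, 24 of 42 at 30 h (57.1%, 42.2 to 70.9%) and 29 at 6 h. The next were chromosome 18 from 39000001 to 40000000 with 23 of 47, chromosome 11 from 117000001 to 118000000 with 23 of 65, chromosome 16 from 97000001 to 98000000 with 22 of 46, and chromosome 2 from 102000001 to 103000000 with 21 of 42. The largest share was on chromosome 4 from 105000001 to 106000000, where 15 of 22 regions were missing (68.2%, 47.3 to 83.6%). By share it was followed by chromosome 19 from 58000001 to 59000000 with 13 of 22, chromosome 5 from 99000001 to 100000000 with 17 of 29, the chromosome 13 window named above, and chromosome 2 from 133000001 to 134000000 with 12 of 21. The highest share of any window, 68.2%, lay within the range of the highest shares in the shuffles, 55.4% on average and 76.2% at most, and single windows were not compared with shuffles at their own size. The most new regions at 30 h were on chromosome 19 from 10000001 to 11000000, 16 of 79. Chromosome 6 from 134000001 to 135000000 had 15 of 51, and 14 were new in each of chromosome 1 from 137000001 to 138000000, chromosome 7 from 25000001 to 26000000 and chromosome 6 from 29000001 to 30000000, of 62, 49 and 48 regions.

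**Figure D3:**
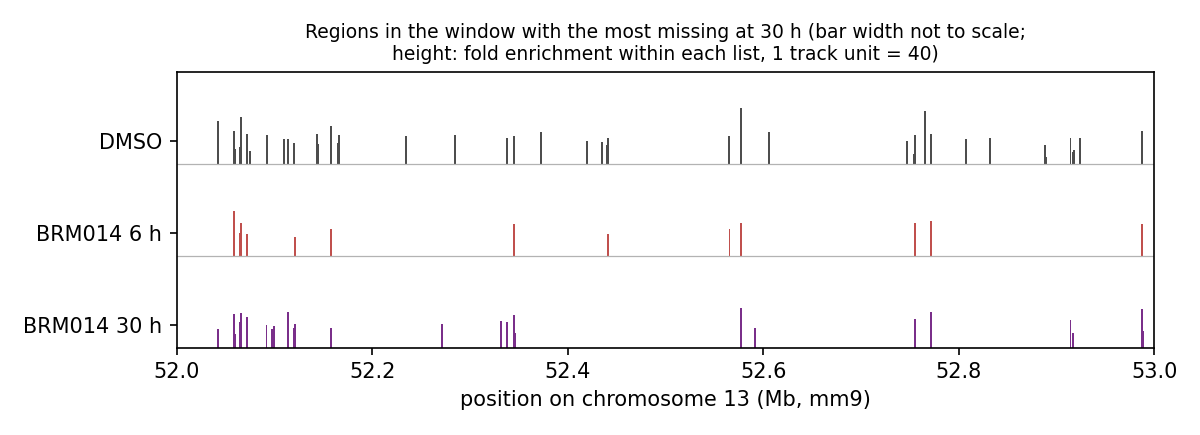
Regions of the DMSO, 6 h and 30 h lists at their summits in the window with the most DMSO regions missing at 30 h (chromosome 13, 52000001 to 53000000, mm9), with bar height as the authors' fold enrichment within each list. Of the 42 DMSO regions, 24 had no 30 h region, and 7 of the 26 regions at 30 h had no DMSO region.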

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

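The alternatives with a score of 1000, with regions within 500 bp counted as shared, with strength ranked on -log10 q and with expected -log10 p were chosen after seeing the data. The differences between width and spacing quartiles weighted over deciles kept their sign wherever they were run, but without weights the spacing quartiles at 6 h lay within each other's intervals, with 44.0% missing in the most isolated and 44.4% in the closest, and the order of the times in new regions turned with lists of equal length. The summit rule, the -log10 q minimum of 5 and all chromosomes moved no value beyond its interval, the last because the lists hold only chromosomes 1 to 19 and X. Values are given as DMSO regions missing at 6 h, at 30 h and at both times, then new regions at 6 h and at 30 h, then the widest minus the narrowest quartile missing at 6 h and at 30 h in points. With an overlap of at least 50% of the region they were 46.0%, 28.4% and 25.7%, then 7.93% and 18.6%, then -31.0 and -19.3. With every entry counted they were 35.6%, 20.6% and 18.7%, then 5.04% and 13.0%, then -51.1 and -33.7. With a score of 1000 they were 28.5%, 14.1% and 12.3%, then 0.903% and 4.62%, then -33.4 and -18.4. With regions within 500 bp shared they were 41.5%, 24.5% and 22.2%, then 6.92% and 16.8%, then -35.7 and -23.6. With 25922 regions in every list they were 23.1%, 19.9% and 14.9%, then 22.3% and 19.4%, then -30.2 at 6 h, the 30 h value staying within its interval; equal lists make missing and new regions nearly equal in number by construction, and remove the weakest regions of the longer lists. With deciles of -log10 q the width differences were -9.87 and -7.02. For the other alternatives the cause was not tested. Of the other values, 18 moved beyond their interval and 18 did not. The 10 named missing and 10 named new regions stayed so under the overlap of at least 50%, the summit rule and the 500 bp rule. No paired analysis was possible because each list holds both replicates of its group together, and for the same reason no replicate was left out in turn. The narrower and wider promoter limits, the stricter and wider sequence settings and the shorter distance to genes were not run, since no mm9 genome or annotation was used. Depth limits the weak regions most, the 6 h list having 63.0% and the 30 h list 80.7% of the depth of the DMSO list.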

Other observations

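The data had been examined before the ranking on -log10 q and the expected pileup were chosen, and the tests chosen only after the result was seen were those of the highest expected pileups, of a single factor on all DMSO pileups, of the pileups found over those expected, of expected -log10 p, and of losses within joint classes of -log10 q and fold enrichment.

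Regions that were kept were also called narrower after treatment. In the 23273 DMSO regions that matched a single 6 h region, the width at 6 h differed by a median of -66 bp and 76.3% of those that changed were narrower (75.8 to 76.9%). In the 30480 matched at 30 h the median was -34 bp and 67.7% were narrower (67.1 to 68.2%). Summits lay close to those in DMSO, with a median distance of 12 bp at 6 h and 10 bp at 30 h. These widths were not corrected for the lower depth of the treated lists. The entry with the highest -log10 q was the same in every list, on chromosome 5 from 60433931 to 60434389 in the DMSO list, with a fold enrichment of 54.6 in DMSO, 54.0 at 6 h and 54.1 at 30 h. Its -log10 q was 4559 in DMSO, 5650 at 6 h and 5009 at 30 h, higher in the treated lists despite their lower depth. In the decile of DMSO regions with the highest -log10 q, 56 of 4231 were missing at 6 h, 22 at 30 h and 13 at both times, and no treated region lay within 500 bp of any of the 13. The first of these were on chromosome 2 from 50705330 to 50706141, at a -log10 q of 562, chromosome 3 from 21484483 to 21485216, at 435, and chromosome 2 from 180077811 to 180078740, at 415. They were picked after their values were seen.

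DMSO regions missing after treatment were mostly weak, as a list cut short by fewer reads or poorer agreement of replicates would give, and in the strongest decile 1.32% and 0.520% were missing at 6 h and 30 h by -log10 q, against 12.7% and 6.24% by fold enrichment. Against such a cut as the whole account, DMSO regions were missing more often than regions of the other treated list at equal expected pileup. The excess was 7.57 points at 6 h and 16.0 points at 30 h (7.18 and 15.6 points at equal expected -log10 p). Both kinds of region met the same list, but each had first passed calling in its own list, at a different depth. Regions at the same expected pileup were therefore not selected alike, so the low bins, where the 6 h list held few regions, cannot decide this. Between pileups of 128 and 152, DMSO regions were still missing more often, 18.1% against 6.04% at 6 h and 11.7% against 0.816% at 30 h. At an expected pileup of at least 256, 1.19% of DMSO regions were missing at 6 h against 0 of 3059 regions of the 30 h list (difference 0.864 to 1.59 points), while the strongest decile of 30 h regions, missing at 6 h in 3.02% by fold enrichment and 0.0260% by -log10 q, decides nothing by itself. For a lower enrichment of all regions alike, the factor on every DMSO pileup that would end the excess was 81% at 6 h and 47% at 30 h. It left 3.68 points at 6 h and 0.365 points at 30 h, at an expected pileup of at least 128. The 3.68 points argue against it as the whole account at 6 h. The 0.365 points at 30 h decide nothing, since only 0.857% of the DMSO regions compared there were missing at all. At 256 or more, with missing regions as 0, the median pileup found at 6 h was 82.9% of that expected (81.0 to 85.1%). That median goes with the factor. The lower and upper quartiles were 47.7% and 109% at 6 h, and 66.4% and 106.5% at 30 h. The regions therefore did not share 1 ratio, but how far 2 lists of 1 treatment would spread is not known. At 30 h the median was 91.7% (91.1 to 92.3%), which argues against a factor of 47%. A smaller drop in all regions at 30 h is not excluded, and the 47% rests on the comparison with 6 h regions. An effect of the inhibitor on particular regions, which was not tested, and differences between libraries unrelated to treatment stay open, since no 2 lists of 1 treatment were compared here.

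The same DMSO regions tended to be missing at both times, 10040 against 7606 for losses independent within deciles of -log10 q. Weakness of DMSO regions, as far as -log10 q and fold enrichment measure it, is not the whole account: within percentiles of -log10 q and quintiles of fold enrichment the count was 1.30 times that of independent losses, against at most 1.02 times in 1000 shuffles. Among strong regions the ratio was 6.09 in the strongest decile by fold enrichment (bootstrap interval 5.60 to 6.62) and 16.5 in the strongest quintile by -log10 q (13.9 to 19.4), or 10.5 within percentiles of -log10 q. These ratios do not bear against irreproducible DMSO regions, which would be missing from both treated lists, so a chance or library effect in the shared DMSO list, which could not be split, cannot be told apart from a loss at both times. A lasting effect of BRM014 on these regions is a candidate explanation that was not tested.

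Neighbouring DMSO regions were missing together at 30 h more often than shuffling gave. Similar strength of neighbours is not the whole account, since 7.97% of adjacent pairs were missing together against at most 7.30% in 1000 shuffles within deciles of fold enrichment, nor is a difference between chromosomes, with at most 7.36% in shuffles that also kept chromosomes. Elements split into adjacent regions were left out by taking pairs over 10000 bp apart, of which 8.35% were missing together. Shuffles within deciles of -log10 q gave at most 7.44%. Those within deciles of fold enrichment gave at most 5.96%, but this decides little, because isolated regions were missing more often at equal fold enrichment. With equal weights over these deciles, 37.0% of the most isolated quartile and 14.7% of the closest were missing at 30 h. Over deciles of -log10 q these shares were 28.0% and 23.7%, a smaller difference that the -log10 q shuffles did not account for either. Copy number or coverage that differs over stretches smaller than a chromosome may still account for the pairs missing together. A response of whole neighbourhoods to the inhibitor may do so too, and neither was tested. The excess was small. Within deciles of -log10 q and chromosomes it was 1.21 times the mean of the shuffles for pairs over 10000 bp apart and 1.15 times for all pairs. At 6 h these ratios were 1.07 and 1.05.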
